A study of Arabidopsis thaliana with 12 samples.

How the data were processed

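RNA of Arabidopsis thaliana, ecotype Columbia 0, had been measured on expression arrays, with 6 arrays of the wild type (WT) and 6 of the psao mutant, per the labels. The molecule was total RNA, per the labels. Tissue, growth, labelling, array manufacture, background treatment and any averaging of spots were not given in the sources used here. Groups and array numbers 1 to 6 were taken from the sample titles.

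The deposited value table held 1 intensity per probe and array for 3439 probes. The deposited intensities were never negative and held exact zeros, and in every column the brightest probe stood at 100, so each array had been scaled to its own brightest probe. What the authors did before that scaling was not given in the sources used here. The scale is therefore relative within an array, and no depth or background level could be read from it. For arrays, their number limits the precision.

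Probe names came from the platform annotation, which listed 1562 of the probes. Of these, 692 were paired with 1 gene and 870 with several, and the other 1877 probes were not listed and stay unnamed here. Names of 1-gene probes were updated through the RefSeq gene table of assembly TAIR10.1, where 690 matched. No gene was named from a probe paired with several. Genome positions are not printed, because no genome build was named for the array.

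Intensities were log2 transformed with zeros set missing, and a probe needed at least 4 values in each group, which left 3187 probes and took out 252. The choice of scaling was fixed in advance: arrays whose log2 medians lay within 0.1 of one another would have been used as deposited. The medians ranged over 1.15 log2 units, so arrays were quantile normalized with limma 3.58.1 in R 4.3.3. Levels in the text are means of these log2 values with their SD, and zeros do not enter them, so a fold of a dim probe rests on the arrays with a signal.

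The psao and WT arrays were compared with lmFit and eBayes of limma, two-sided, psao minus WT, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05 on the adjusted p. Adjusted p-values in the text come from this limma fit unless another test is named. Measures of single arrays were compared with an exact two-sided permutation test. A total of 17 gene lists with 259 loci covered photosynthesis, other plastid functions, stress markers and markers of seeds and roots. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, in its form for ranked statistics because values were missing. Camera with an estimated correlation and fry were run beside it, on values with missing entries set to the group mean. The design, gene lists, most of the other settings and the rule for named genes were fixed before the data were examined.

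By that rule PSAO would be named in every case. Named with it were, among called probes with 1 gene and at least 5 psao arrays on the side of the WT mean given by the fold change, the 10 with the largest rise and the 10 with the largest fall. From each list, up to 3 called members with the lowest p were named, or otherwise the member with the lowest p. No 1-gene probe was paired with PSAO, so the planned check of the genotype labels by its transcript was not analysed here.

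WT and psao arrays share the numbers 1 to 6 in their titles. Deviations from the group means of the 6 same-numbered WT and psao arrays correlated across probes with r from 0.144 to 0.239, mean 0.193, so the numbers were taken to pair the arrays, although the labels do not say what a number stands for. Fits with the number as a block stand beside the main fit where they changed a call.

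Within a genotype, arrays 1 and 2, 3 and 4, and 5 and 6 resembled each other more than other arrays, and each such set is called a couple. This was seen in the data and is not in the labels. Fits with the arrays of a couple averaged (avearrays), or with couples as a random block (duplicateCorrelation, statmod 1.5.0), were therefore added after seeing the data. Other alternatives covered scaling, a filter on dim probes, an offset before the log, array weights, the variance prior, an ordinary test, a stricter threshold, centring by probe number and leaving out each array in turn. Centring by probe number is called centring by position below, and the layout of the array it uses was assumed.

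The fit was tested on simulated data for the psao and WT comparison with 3187 probes, of which 200 were changed. Each setting was a single draw, with no error shared between WT and psao arrays. With independent arrays it called 119 probes, 5.04% of them false, and recovered 34% of changes of log2 size 1 and 79% of size 2. With couples averaged it called 86 probes, 5.81% of them false, and recovered 14% and 67%. When the arrays of a couple shared error with a correlation of 0.701, as estimated from the data, the fit of all arrays called 268 probes, 42.9% of them false. Couples averaged then gave 45 calls, 2.22% of them false, with 4% and 40% recovered. Figures were drawn with matplotlib 3.10.9.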

Results

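Transcript levels were compared between Arabidopsis WT plants and the psao mutant, which lacks PSI-O, a small membrane subunit of photosystem I. Both were of ecotype Columbia 0, and 6 arrays of each were measured. The question was which transcripts differ when this photosystem I subunit is missing. The labels do not say whether arrays came from separate plants or cultures, so p-values measure the spread between arrays, which may be technical. The deposited intensities are relative to the brightest probe of an array, which stands at 100. Median intensities of WT arrays 1 to 6 were 0.0995, 0.0970, 0.180, 0.182, 0.195 and 0.186, and those of psao arrays 1 to 6 were 0.272, 0.273, 0.199, 0.198, 0.246 and 0.245. The mean of these medians was 0.157 ± 0.0455 (SD, n = 6) in WT and 0.239 ± 0.0332 (SD, n = 6) in psao, with an exact two-sided permutation p of 0.00216, the smallest that 6 arrays against 6 can give. This permutation test counts every array as separate, whereas the medians lay close together within couples of arrays. The p is therefore too small if the arrays of a couple are not independent. Zeros made up 14.5% and 15.1% of WT arrays 1 and 2 and between 4.22% and 7.33% of the other arrays. No 1-gene probe was paired with PSAO itself, so its transcript was not analysed here.

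Many transcripts differed between psao and WT, about equally often in each direction. Of 3187 probes tested with limma, 949 passed the adjusted threshold, 472 higher and 477 lower in psao, and 584 of them changed at least 2-fold (351 higher, 233 lower). Among 628 tested probes with 1 gene, 176 changed, 100 upward and 76 downward. The named genes ranged from AT5G40030, 9.66-fold higher in psao, to AT4G02580, a 24 kDa subunit of mitochondrial complex I, 12.2-fold lower over quantile-normalized arrays. For 608 called probes all psao arrays with a signal lay outside the range of the WT arrays. This held for 19.7% of all tested probes, where chance gives 0.333% at their numbers of arrays if arrays are independent. The balance depended on scaling: with values as deposited, the median of all probes shifted by 0.43 log2 units toward psao and 763 of 986 called probes (77.4%) were higher, against 49.7% after quantile normalization. Changes are given relative to the normalized distribution. Arrays 1 and 2, 3 and 4, and 5 and 6 of a genotype deviated together and are called couples, and with each couple averaged, 3 values against 3, 57 probes passed, 45 higher and 12 lower. Couple means did not overlap between the genotypes in 34.5% of 2990 probes, where chance gives 10% for 3 against 3. This 10% is an average over all splits of the couple means, and the share was not computed for the other splits. All probes share the same couples, so the excess cannot exclude chance in how couples fell into groups.

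The 10 largest rises among named genes included a kinesin-like protein, a RAB acceptor and a pentatricopeptide repeat protein. AT5G40030 rose by 3.27 ± 0.62 log2 units (SE), from -5.79 ± 1.44 (SD, n = 6) in WT to -2.52 ± 0.83 (SD, n = 6) in psao (limma adjusted p = 0.00237), and all 6 psao arrays lay above the WT mean. AT5G46560 rose by 2.78 ± 0.22, from -2.03 ± 0.41 (SD, n = 5) to 0.75 ± 0.21 (SD, n = 6), with an adjusted p in limma of 1.54e-05. AT5G40140 rose by 2.57 ± 0.34 (adjusted p = 0.000247) and AT3G06870 by 2.40 ± 0.43 (adjusted p = 0.00168). The rise of AT3G06870 was 3.83 in arrays 1 and 2, and with arrays 3 to 6 alone it was 1.68 and passed. AT4G14330, the kinesin-like protein, was 5.87-fold higher. PRA1.B6, of the prenylated RAB acceptor family that acts in vesicle trafficking, was 5.17-fold higher, and AT1G27610 was 5.08-fold higher. AT2G23160 was 6.95-fold and AT5G11010 6.56-fold higher, with wide spreads in WT (SD 2.13 and 2.43 log2 units). The rise of AT5G11010, 2.71 log2 units, was 1.71 without WT replicate 1 and 1.36 with arrays 3 to 6 alone, and it passed in 16 of 27 alternatives. AT2G46050, the pentatricopeptide repeat protein, was 4.96-fold higher (adjusted p = 0.0376). With the array number as a block its adjusted p was 0.0649, and over all alternatives it ranged from 0.0120 to 0.306. Its rise of 2.31 log2 units was 1.59 without WT replicate 2. With arrays 3 to 6 alone it was 1.08 and did not pass (limma adjusted p = 0.0880). With an offset before the log, which keeps zeros, AT4G14330 rose less, by 1.65 against 2.55, and did not pass (limma adjusted p = 0.0886, with a range of 0.000990 to 0.110 over all alternatives). AT5G40030 and AT2G23160 passed with the offset, with rises of 2.31 and 1.72 in place of 3.27 and 2.80. With couples averaged, 3 of the 10 rises passed: AT5G46560, AT5G40140 and AT1G27610. With couples as a random block AT1G27610 did not pass (limma adjusted p = 0.0900). In WT, 8 of the 10 lay below the median probe intensity of 0.199.

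The 10 largest falls included a subunit of respiratory complex I, a peptidyl-tRNA hydrolase and PIFI. AT4G02580, the complex I subunit, fell by 3.60 ± 0.57 log2 units (SE), from -2.82 ± 0.43 (SD, n = 6) in WT to -6.42 ± 1.47 (SD, n = 6) in psao (limma adjusted p = 0.000747), and all 6 psao arrays lay below the WT mean. The change of AT4G02580 was -2.61 with an offset before the log and -2.79 with values as deposited, and passed in both. AT1G18440, the peptidyl-tRNA hydrolase, which recycles tRNA in translation, was 9.85-fold lower over the 4 WT and 5 psao arrays above zero. Its change of -3.30 log2 units was -0.75 with an offset that keeps the zeros (limma adjusted p = 0.205). It passed in 17 of 27 alternatives, with adjusted p from 0.00637 to 0.214, and not with values as deposited, cyclic loess or array weights. AT1G62780 fell by 2.61 ± 0.28, from -1.34 ± 0.43 to -3.95 ± 0.52 (adjusted p = 6.02e-05). PIFI, a chloroplast protein needed for the post-illumination rise of chlorophyll fluorescence and tied to the NDH route of electron flow, fell by 1.62 ± 0.32, from -3.59 ± 0.50 (SD, n = 6) to -5.21 ± 0.65 (SD, n = 6), with an adjusted p in limma of 0.00321. With values as deposited the change of PIFI was -0.80 and did not pass (adjusted p = 0.158, with a range of 0.000277 to 0.158 over all alternatives). AT5G44150 was 7.49-fold lower, AT1G50000 7.02-fold, AT4G16060 4.25-fold and AT1G01080 2.86-fold. The change of AT5G44150, -2.90 log2 units, was -2.29 without psao replicate 2, -1.50 with the offset and -2.17 as deposited, where it did not pass. AT1G01080 changed by -0.82 with values as deposited, against -1.52, and still passed. AT1G50000 passed in 9 of 27 alternatives, with adjusted p from 0.0163 to 0.318, and its change of -2.81 was -2.06 without psao replicate 6. AT4G16060 changed by -1.33 with arrays 3 to 6 alone, against -2.09, and did not pass. AT1G33250 was 3.23-fold lower over 4 WT and 6 psao arrays. WT arrays 1 and 2, deposited at 0 and left out, lay below psao arrays 1 and 2 at 0.0922 and 0.0635, the opposite direction. With the offset its change was -0.37 in place of -1.69 (limma adjusted p = 0.722, with a range of 0.00302 to 0.723). The gene iqd32, of the calmodulin-binding IQ-domain family, was 4.01-fold lower (adjusted p = 0.0299). With the array number as a block its adjusted p was 0.0567, within a range of 0.000233 to 0.326 over all alternatives, of which 13 of 27 passed. WT arrays 1 and 2, deposited at 0.0207 and 0, each lay below the psao array of the same number, at 0.114 and 0.0181. After quantile normalization, and with the zero of WT array 2 left out, that couple fell by 0.73. WT array 1 then stood at -4.55, and psao arrays 1 and 2 at -3.77 and -6.78. With the offset the change of iqd32 was -1.27 log2 units, a smaller fall, and did not pass (limma adjusted p = 0.104). With couples averaged, AT1G62780 alone of these 10 falls passed. In psao all 10 lay below the median probe intensity of WT, 0.199, so that these folds rest on dim signals.

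**Figure D1:**
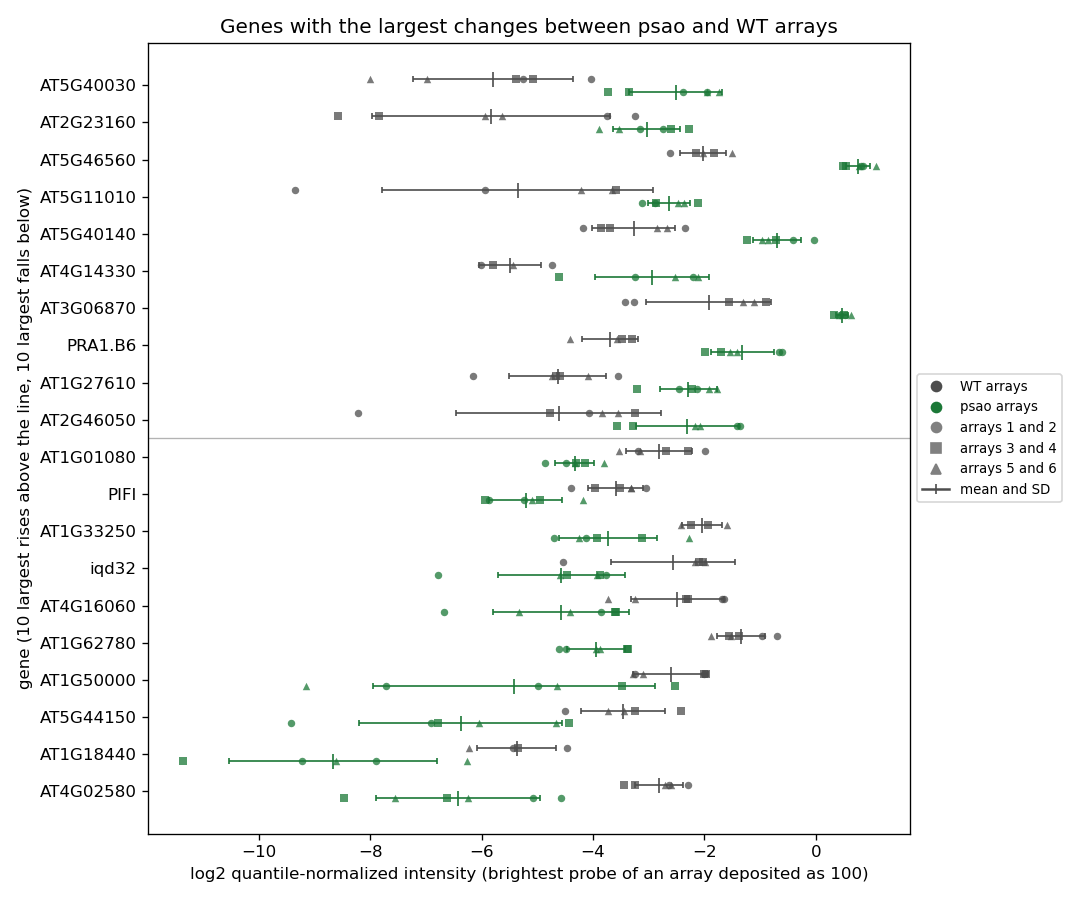
Log2 quantile-normalized intensity (horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall in psao (vertical axis). Each point is an array, grey for WT and green for psao, with 1 shape per couple of arrays, and bars show the mean and SD; in 12 of the 20 genes the psao and WT arrays with a signal do not overlap.

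The gene lists, of photosynthesis and of other functions, were thinly covered: 15 of the 259 listed loci had a measured 1-gene probe, in 7 of the 17 lists. The measured photosystem and antenna genes did not pass the test after quantile normalization. PSAN, a lumenal subunit of photosystem I that takes part in docking plastocyanin and the only measured member of its list, stood at 2.58 ± 0.31 log2 units (SD, n = 6) in WT and 2.15 ± 0.59 (SD, n = 6) in psao (limma adjusted p = 0.244). Its difference was -0.44, and -1.02 under median centring, where it passed (adjusted p = 0.00433, with a range of 0.00433 to 0.535 over all alternatives). It was -0.27 without psao replicate 4, and 0.01, -1.14 and -0.17 in the 3 couples. LHCB1.5, a protein of light-harvesting complex II and also the only measured one, had a difference of -0.19 (adjusted p = 0.6252), which was -0.84 under median centring and changed sign under array weights. Without WT replicate 1, and likewise without WT replicate 2, it was -0.03. Of photosystem II, PSBW differed by 0.17 (adjusted p = 0.405), with the opposite sign under median centring. Centred by position it differed by 0.62 and passed (adjusted p = 0.0317, with a range of 0.0317 to 0.730 over all alternatives). PSBY differed by -0.07 (adjusted p = 0.839), with the opposite sign as deposited (0.02) and with arrays 3 to 6 alone (0.09).

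Of the Calvin cycle, 1 of 2 measured genes fell. SBPASE, sedoheptulose-bisphosphatase, went from -0.05 ± 0.21 (SD, n = 6) in WT to -0.70 ± 0.44 (SD, n = 6) in psao, a change of -0.66 ± 0.22 (SE, limma adjusted p = 0.0384), with all 6 psao arrays below the WT mean. With the array number as a block the adjusted p was 0.0513, and it ranged from 0.00538 to 0.359 over all alternatives. PRK, phosphoribulokinase, differed by -0.48 (adjusted p = 0.135) and by -0.22 with arrays 3 to 6 alone. Of chlorophyll synthesis, 1 of 2 rose: CHLP, the geranylgeranyl reductase that makes the phytyl chain of chlorophyll, went from 0.50 ± 0.21 (SD, n = 6) to 1.05 ± 0.18 (SD, n = 6), 1.46-fold higher with a limma adjusted p of 0.0214. Under median centring the change of CHLP was 0.17 and did not pass (adjusted p = 0.598, with a range of 0.00150 to 0.598 over all alternatives). CHLM, a methyltransferase of the same pathway, differed by -0.09 and did not pass, and its direction depended on the arrays and the scaling. It was 0.44 with values as deposited, and -0.54 with arrays 3 to 6 alone, where it passed (limma adjusted p = 0.0445, with a range of 0.0445 to 0.995 over 21 alternatives). Adjusted over the list alone, 1 gene passed in each of these lists. Of the antioxidant list neither measured gene passed: the peroxiredoxin PRXIIE differed by 0.89 (adjusted p = 0.0792, and 0.0347 to 0.634 over all alternatives, passing only without WT replicate 3) and the thioredoxin reductase NTRC by 0.16. The difference of PRXIIE came mostly from arrays 1 and 2: it was 2.39, -0.11 and 0.40 in the 3 couples and 0.14 with arrays 3 to 6 alone. NTRC stood at -0.09 with arrays 3 to 6 alone. With couples averaged, neither SBPASE nor CHLP passed.

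The plastid ribosome was the only list with enough members for a set test, with 5 of 36 measured. RPS6 fell by 0.91 ± 0.30 log2 units (SE), from -2.40 ± 0.50 (SD, n = 6) to -3.31 ± 0.51 (SD, n = 5), with an adjusted p in limma of 0.0404. It passed in 14 of 28 alternatives, with adjusted p from 0.00443 to 0.571, and not with couples averaged or with values as deposited, where the change was -0.30. The other 4 did not pass, with differences of -0.62 for RPL34, -0.41 for RPL17, -0.34 for RPS10 and 0.16 for RPL5. With arrays 3 to 6 alone these were -0.12, -0.32, 0.02 and -0.06. RPL17 passed in 2 of 21 alternatives, median centring among them (limma adjusted p = 0.0170, with a range of 0.0170 to 0.417). RPL5 passed centred by position, where it rose by 0.62 (limma adjusted p = 0.0362, with a range of 0.0362 to 0.917 over 21 alternatives). Adjusted over the list alone, 0 of the 5 passed in limma, with 2 at an unadjusted p under 0.05. The list had a mean difference of -0.42 and a median of -0.41, and did not stand apart from other probes (camera p = 0.308, and p = 0.312 with an estimated correlation). In fry, which tests whether members move one way on balance and not against other genes, the p was 0.0252. With values as deposited the mean difference was 0.02, and with arrays 3 to 6 alone -0.29.

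The other 10 lists had no measured 1-gene probe. They were light-harvesting complex I, electron transport and ATP synthase, LHC-like proteins, plastid proteases, plastid import, starch, carotenoids, photorespiration, stress markers, and seed and root markers. Signs of stress or of other tissues in the samples were therefore not analysed here.

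The couples of arrays differed in how far psao stood from WT before scaling. Deposited log2 medians of psao exceeded those of WT by 1.14 in arrays 1 and 2, 0.12 in arrays 3 and 4 and 0.33 in arrays 5 and 6. Fitted separately with 2 arrays of each genotype, the couples gave 987 calls of 2600 probes, 969 of 3055 and 976 of 3126. The share called was thus highest in arrays 1 and 2. With the couple as a block over all 12 arrays, 1364 were called. With couple means and the same block, 0 were called in limma, with 862 at an unadjusted p under 0.05. The labels do not say whether the arrays of a couple are repeats of 1 RNA, and the counts from single arrays take them as replicates. AT5G46560 rose by 3.44, 2.51 and 2.70 log2 units in the couples in this order and AT1G62780 changed by -3.71, -1.92 and -2.21, whereas AT2G23160 ranged from 0.55 to 5.76. Fold changes of different couples correlated across probes, which are not independent replicates, with r of 0.345, 0.456 and 0.595.

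**Figure D2:**
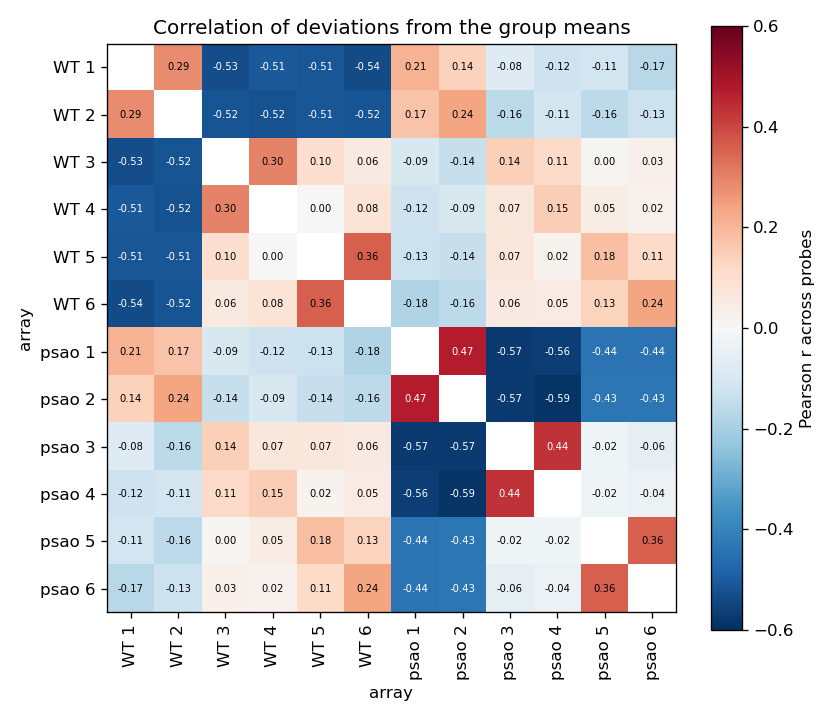
Pearson correlation across probes (colour and printed value) between the deviations of each pair of the 12 arrays (both axes) from their group means. The 6 couples within a genotype have r from 0.285 to 0.471, and same-numbered WT and psao arrays have r from 0.144 to 0.239.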

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

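The tests of couples, of dim probes, of arrays 1 and 2 and of position were chosen after the related results had been seen, and the counts of other splits before.

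In AT2G46050, WT replicate 2 stood at -8.22 log2 units, far below the nearest other WT array at -4.78. In iqd32, WT replicate 1 stood at -4.55 with the nearest other of 5 WT arrays at -2.17, and psao replicate 2 stood at -6.78 with the nearest other at -4.59. In all, 60 sets of values were tested for a far sample, and chance alone flags about 1 in 20 of them, so that 3 would be expected.

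The first pattern is the large number of probes that differ between psao and WT. Other splits of single arrays gave far fewer calls. Among the 32 splits that part all 6 same-numbered pairs, 1 (the real one) gave 949 calls and the highest other gave 13. Among 100 drawn splits again 1 gave as many, with 0 as the highest other. These splits break up couples whose residuals correlate, so they cannot exclude chance in how couples fell into groups. With couples averaged, the real split gave 57 calls and the highest other 0, 1 of 10 splits, which are too few for a share under 0.05. Treatment of dim signals as the source of all calls was argued against by 437 of the 1062 brightest probes being called. Of the 1063 dimmest, 194 were called, so the share was 2.25 times as high among the brightest (95% interval 1.95 to 2.61). This ratio cannot show that dim calls are free of such an effect, since the spread of dim and bright probes was not compared. Called probes had a median absolute log2 change of 1.46 among the dimmest and 1.01 among the brightest. Treatment of dim signals therefore stays open as a source of calls among dim probes. WT arrays 1 and 2 as the source of all calls were argued against by 773 of the 949 recurring, in the same direction, among 1215 calls with arrays 3 to 6 alone, which are 2 couples per genotype taken as separate arrays. A difference of genotype and any difference in growth, harvest or preparation of the 2 plant lines stay open, since the labels give no second source of either line.

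The second pattern is the drop from 949 to 57 calls when the arrays of a couple are averaged. A candidate explanation is that arrays of a couple share error, as repeat hybridisations of 1 RNA would: residuals within couples had a consensus correlation of 0.701. In simulated arrays sharing error to this degree, 115 of 268 calls in the fit of all arrays (42.9%) were false. The simulation was a single draw that changed 200 of 3187 probes, and the false share depends on that number. It gave WT and psao arrays no error in common, whereas their deviations correlated in the data. It therefore gives no false share for the 949 calls. Deviations of WT and psao arrays correlated more within a couple than between couples, by 0.233 in mean r, which is consistent with a step of processing that both genotypes of a couple went through together. A shared set of plants would give the same values, and no biological explanation was tested.

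The third pattern is that fold changes of probes at fixed distances in number were alike. The highest r was 0.176, between probes 12 numbers apart (one-sided permutation p = 0.001, the smallest that 1000 permutations can give). It was 0.0841 between adjacent probes, 0.154 between probes 6 numbers apart and 0.148 at the largest distance tested. The likeness was thus weakest between adjacent probes. Mean levels of probes were alike too, with r of 0.171 at 12 numbers apart and 0.229 at the largest distance. A regional trend over the array could add to the fold changes. Centring by position left 880 calls, of which 672 were among the original calls. The part of a trend that this centring removed was therefore not the whole source of the calls. After that centring r between probes 12 numbers apart was 0.0858, above the highest of the 1000 permutations of uncentred values (0.0833). It was -0.0223 between adjacent probes, 0.0460 at 6 numbers apart and 0.0522 at the largest distance. Each of these lay below the highest permutation at its distance. A trend that remained was not excluded as a source, and grouping of related genes on the array was not tested.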

How the results depend on the processing

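Averaging couples, couples as a random block, arrays 3 to 6 alone, an offset at the 10th percentile and centring by position were added after seeing the data. The count of 949 called probes stayed within 1.5 times under the other scalings, filters, priors and weights run (862 to 1336 calls) and from 788 (without psao replicate 5) to 938 when single arrays were left out. It was 466 at an adjusted p under 0.01, 330 with couples as a random block and 57 with couples averaged. Couples averaged with the couple number as a fixed replicate block gave 0 calls in limma with 862 at an unadjusted p under 0.05, with fewer values and fewer degrees of freedom. Pairing the arrays by number as a fixed replicate block gave 1090 calls, 852 of them among the 949, and as a random replicate block 1141. The fixed block ended the calls of AT2G46050, iqd32 and SBPASE and changed no other call among the 27 named genes. Couples averaged ended 19 of 23 such calls, with every direction kept. Among the scalings, values as deposited ended 7, median centring 4 and cyclic loess 3. The 7 ended as deposited were all falls, and each was smaller there. With that scaling the median of all probes was shifted by 0.43 log2 units toward psao, which makes falls smaller. For the calls ended by the other 2 scalings the cause was not tested.

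The plastid ribosome list had a mean difference of -0.42, from -0.53 to -0.29 when single arrays were left out. It was 0.0229 with values as deposited, where the median of all probes shifted upward. Of the tests of this list, fry alone passed the threshold, at the same mean of -0.42. Differences below the threshold changed sign, among the 27 named genes, in PSBW under median centring (-0.29) and in LHCB1.5 under array weights (0.00697) and with arrays 3 to 6 alone (0.0521). Other list members did so too: PSBY, RPL5, RPS10 and NTRC with arrays 3 to 6 alone, and PSBY, CHLM, RPL34 and RPS10 as deposited. The cause was not tested. The planned offset at the 5th percentile was not run, because that percentile is 0. The planned settings for PSAO were not run, as no probe names it. Without a stated background, signal over background set no limit that could be given, and folds of probes with zeros rest on fewer arrays.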

Other observations

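All genes and lists in this part were chosen after their values were seen.

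Of the 57 probes that also passed with couples averaged, 12 name 1 gene, 10 higher and 2 lower in psao. With couples averaged, their limma adjusted p lay between 0.0348 and 0.0491. With couple means and the couple as a block, no probe passed. The adjusted p-values of single genes that follow come from the fit of all arrays unless another is named. That fit takes the arrays of a couple as replicates. PYG7 (AT1G22700), a thylakoid protein needed to assemble photosystem I, rose by 1.91 ± 0.27 log2 units (SE), from -4.05 ± 0.65 (SD, n = 5) to -2.14 ± 0.16 (SD, n = 6), with a limma adjusted p of 0.000538. Its rise was 1.96, 2.09 and 1.85 in the 3 couples. AT4G24930, a protein of the thylakoid lumen, rose by 2.05 ± 0.27 (adjusted p = 0.000246), by 2.05, 2.06 and 2.02 in the couples. AT3G23940, dihydroxyacid dehydratase of branched-chain amino acid synthesis, was 4.76-fold higher. AT1G49850, AT1G72020, AT5G63290 and AT3G57440 were 4.09-fold, 3.92-fold, 3.53-fold and 2.96-fold higher. AT5G46560, AT5G40140 and AT1G27610 completed the rises, and AT1G27610 did not pass with couples as a random block (limma adjusted p = 0.0900). SRX, sulfiredoxin, which reactivates oxidised peroxiredoxins, fell by 2.69 ± 0.43 with signal in 5 WT and 4 psao arrays (adjusted p = 0.0018) and by 1.79 with an offset that keeps zeros, and AT1G62780 was the other fall. Outside this set, GLDH, the last enzyme of ascorbate synthesis, was 2.14-fold lower (adjusted p = 0.00284), and CUTA, among the brighter probes, fell by 0.89 (adjusted p = 0.000553), both in 6 of 6 psao arrays. Centred by position the changes were -0.58 for GLDH and -0.54 for CUTA, and both passed (limma adjusted p = 0.0479 and 0.0288). Under median centring they were -1.35 and -1.50.

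A list of genes around the chloroplast NDH complex, which carries cyclic electron flow around photosystem I, had 6 measured members: the subunits NdhN and NdhS, the assembly factor CRR41, the RNA editing factors CRR21 and OTP85, and PIFI, tied to the function of the complex. In limma 3 rose: NdhS by 1.09 (adjusted p = 0.000487), CRR41 by 1.55 (adjusted p = 0.00514) and OTP85 by 0.81 (adjusted p = 0.0437). With the array number as a block, the limma adjusted p of OTP85 was 0.0552, within 0.0552 to 0.210 over 4 other fits (this block, couples averaged or as a random block, and arrays 3 to 6 alone). PIFI fell by 1.62, and the other 2 did not pass, with -1.36 for NdhN and 0.97 for CRR21. NdhS did not pass under median centring, where it rose by 0.43 (limma adjusted p = 0.195, with a range of 0.000536 to 0.195 over 21 alternatives). CRR21 passed in 3 of 21 alternatives, values as deposited among them (limma adjusted p = 0.0186, with a range of 0.0186 to 0.283). With an offset that keeps zeros NdhN passed (limma adjusted p = 0.0487, against 0.0634 to 0.425 over the 4 other fits) and OTP85 did not. NdhN passed in 2 of 21 alternatives, the other being centring by position, where it changed by -1.86 (limma adjusted p = 0.0161). Its change was -0.75 with values as deposited, and from -1.58 to -0.83 when single arrays were left out. With couples averaged, 0 of the 6 passed in limma and 3 had an unadjusted p under 0.05. All 6 passed adjusted over the list alone, which is no independent evidence for a list picked from these data. Whether NDH genes moved one way as a group stays open: the camera p was 0.209 (p = 0.295 with an estimated correlation), and a test of a list picked from these data decides nothing. A list of lumen and photosystem assembly proteins had 5 measured members. Of these PYG7 and AT4G24930 rose and PPD3 fell by 0.95, a call that ended with couples averaged and with couples as a random block (limma adjusted p = 0.167 and 0.0666, within 0.0274 to 0.167 over 4 other fits), while LPA19 (-1.27) and PSB27 (-0.03) did not pass. The change of PPD3 was -0.57 with arrays 3 to 6 alone and -0.39 with values as deposited, where it did not pass. The near-zero difference of PSB27 hid unlike couples: it was -0.60 with arrays 3 to 6 alone (limma adjusted p = 0.0643, with a range of 0.0643 to 0.990 over 21 alternatives) and 0.08 with values as deposited. LPA19 passed in 10 of 21 alternatives, among them with the array number as a block (limma adjusted p = 0.0102, within 0.000933 to 0.273 over 4 other fits). Movement of this list as a group stays open for the same reason, with a camera p of 0.284 and p = 0.504 with an estimated correlation. Whether single members respond to the loss of PSI-O was not tested beyond these arrays.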
